A study of Mus musculus with 6 samples.

How the data were processed

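The samples were mouse embryonic stem cells of strain 129P2/Ola, 6 in all. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) for histone H3 phosphorylated at serine 10 (H3S10p) was done in 2 libraries from cells held for 20 hours in aphidicolin, an inhibitor of replicative DNA polymerases, and released for 3 hours. Total RNA depleted of ribosomal RNA was sequenced in 2 untreated libraries and 2 libraries from cells given the Aurora kinase inhibitor ZM-447439 for 48 hours. Samples were grouped by their titles. Nothing in the labels says whether libraries of one group came from separate cultures, so any p-value over libraries measures only the spread between these samples, which may be technical.

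The mouse build is mm9, with Bowtie named for both assays and DESeq for RNA, per the submitters' processing notes, as used here without version or role. Peaks were called separately in each ChIP library with MACS, per the file headers. The MACS version, its threshold and any control library are not given in the sources used here. Each peak carries a score that the authors deposited as the peak caller wrote it. The lowest score was 50.01 in both lists, and the scale is not named, so scores were used to rank and filter peaks within a list, to order shared peaks by the mean of their scores, and otherwise only as listed values. Score values set side by side between the libraries are descriptions, since their scale and the read depth are unknown. Peak positions are given here counted from 1, on mm9.

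For RNA, the values used here were the authors' own comparison, one row per gene. Per the file header, the authors deposited for each gene the mean, lowest and highest log2 fold change over its changed transcripts, treated over untreated. The header names log2 only for the mean, and the lowest and highest values bracket it on the same scale. The header also names a smallest p-value, without saying over which transcripts or whether the authors adjusted it. Group means of a normalized expression signal called NE were deposited with their SD, the SD to 3 decimals. The formula of NE and what the SD was taken over are not given in the sources used here. Values per RNA library were not analysed here, so the planned tests on counts or on normalized values per library were replaced by the authors' listed statistics. The gene identifiers of all 10 genes matched their symbols in a RefSeq gene table, which was on another mouse build (GRCm38) and was used for names only.

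From the peak lists, a peak counted as shared when it overlapped a peak of the other library by at least 1 bp. The number shared was set against 1000 random placements of the library 1 peaks within their chromosomes, from 3 Mb (the assembled start), or from the first base on Y and the mitochondrial sequence, to the last called base. Peak density was taken over the 19 autosomes and X as peaks per Mb of that span, with exact Poisson 95% intervals. Shares of peaks have Wilson 95% intervals. Both cover counting error only, and neighbouring peaks are not independent. Density in the first 10 Mb of assembled sequence was compared with the rest of each chromosome by a two-sided sign-flip permutation test over chromosomes with 100000 resamples. Chromosomes are not biological replicates. Peaks with gaps of at most 10 kb were joined into clusters and set against 1000 random placements. Read depth per library is unknown from these lists. Because no second ChIP condition or input library was analysed here, no ChIP comparison between conditions was made.

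The overlap, density and cluster calculations were tested on simulated peak lists of the real lengths, 11067 and 12261 peaks. With 30% of peaks planted as shared, 30.3% were recovered. Among 40 pairs of unrelated lists, 3 had a random-placement permutation p below 0.05. These lists were placed at random within chromosomes, as in the test itself. They lack the regional differences in density of the real lists, so the test was not checked under such differences. A density planted at 2 times that of the rest was recovered as 1.98 times. After 1000 neighbours were planted in a list with 9.14% of peaks in clusters, 24.4% were in clusters where 24.2% was computed beforehand. In the list of 11067 peaks, shares of 20% and 40% planted in the lowest and highest 25% by score within groups of width were recovered as 19.2% and 39.1%. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures matplotlib 3.10.9.

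The comparisons, the alternatives and the naming rule were fixed before the data were examined, apart from those named as added later. The rule named all genes of a table of 30 or fewer, of which 1 is not reported here, the 5 shared peaks with the highest mean score and the 3 densest 1 Mb windows by the mean of the libraries. Alternatives covered the overlap rule, score filters, list lengths, the width of the region at the chromosome start, the cluster gap, leaving out either ChIP library, and thresholds on the RNA table. The share of peaks at promoters, exons and introns needs an mm9 annotation and was not analysed here.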

Results

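The data comprised 2 H3S10p ChIP-seq libraries and 4 RNA-seq libraries of mouse embryonic stem cells. H3S10p is a phosphorylation of histone H3 deposited mainly by Aurora B, a kinase of dividing cells, and the series placed it in the setting of pericentric heterochromatin. The ChIP libraries came from cells 3 hours after release from a 20-hour aphidicolin block. MACS peak lists held 11067 peaks in library 1 and 12261 in library 2. The RNA libraries were 2 untreated and 2 exposed for 48 hours to ZM-447439, which inhibits Aurora kinases, and their comparison was represented by a table of 10 genes.

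The first question was where H3S10p was called in both libraries. Of the library 1 peaks, 3881 (35.1%, 95% Wilson interval 34.2 to 36.0%) overlapped a library 2 peak, and 3887 of the library 2 peaks (31.7%, 30.9 to 32.5%) overlapped a library 1 peak. Bases covered by both lists made up 18.0% of the bases covered by either. Random placement of library 1 peaks within their chromosomes gave 43.7 ± 6.51 shared peaks (SD over 1000 placements), so the observed number was 88.8 times higher. The one-sided random-placement permutation p was 0.001, the smallest these placements can give. When each peak was shifted by up to 50 kb, a setting added after seeing the data that keeps regional peak density, the mean was 159 shared peaks and the observed number was 24.4 times higher. The overlap therefore exceeded both chance levels, while 7186 peaks of library 1 and 8374 of library 2 were called in that library alone.

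The 20 strongest shared peaks lay at 15 loci (peaks within 0.5 Mb joined), with borders a median of 4 bp apart between the libraries (start and end averaged), although 4 of the peaks differed by 97 to 196 bp. The peak with the highest mean score was on chromosome 9 from 35112691 to 35113286, with scores of 2299 in library 1 and 2322 in library 2. A pair of peaks on chromosome 2 followed, at 98506287 to 98507600 (scores 1909 and 1961) and at 98502278 to 98503257 (1454 and 1493). Next came chromosome X from 139917440 to 139917753 (645 and 710) and chromosome 6 from 103598936 to 103599396 (539 and 765). Among the 20 strongest shared peaks, 8 lay within 0.2 Mb of the assembled start of chromosomes 5, 9, 11 or 12, next to the unassembled centromeric end. Peaks of this strength were rare: only 44 peaks of library 1 (0.398%) and 47 of library 2 (0.383%) scored over 150, and 36 and 41 of them (81.8% and 87.2%) were shared. The median scores of the whole lists were 65.9 and 66.7. Which genes or repeats lie at these positions was not analysed here. Since no input library was analysed, it was not tested whether the peaks, the strongest calls and the 5 named ones included, reflect enrichment of H3S10p. The same limit holds for the overlap between the libraries and for the densities and clusters given below.

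Across all peaks, wide ones were shared more often than narrow ones, most of which were not shared. Shared peaks had a median width of 425 bp in library 1 and 411 bp in library 2, against 268 and 251 bp for peaks called in a single library. In library 1 the share of peaks found in the other library was 13.8% (11.9 to 16.0%) in the narrowest 10% and 59.4% (56.5 to 62.3%) in the widest 10%. In library 2 the corresponding shares were 12.1% (10.4 to 14.1%) and 55.5% (52.8 to 58.3%). Over the whole lists score showed a smaller difference: the lowest 10% by score were shared at 30.6% in library 1 and 27.4% in library 2, and the highest 10% at 37.2% and 32.0%. Wider peaks tended to score lower (Spearman correlations of -0.19 and -0.21 across peaks), so score was also compared within groups of like width, a comparison added after seeing the data. Among the widest 25%, the share rose from 50% (46.3 to 53.7%) in the lowest 25% by score to 64.4% (60.8 to 67.9%) in the highest in library 1, and from 40.03% (36.6 to 43.5%) to 64.4% (60.9 to 67.7%) in library 2. Among the narrowest 25% it was 16.0% (13.5 to 18.96%) and 16.6% (14.1 to 19.6%) in library 1, and 13.4% (11.2 to 16.0%) and 14.4% (12.1 to 17.02%) in library 2. Across the 3897 overlapping pairs, scores in the libraries had a Spearman correlation of 0.11 and widths one of 0.47. These are correlations across peaks, which are not independent replicates.

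**Figure D1:**
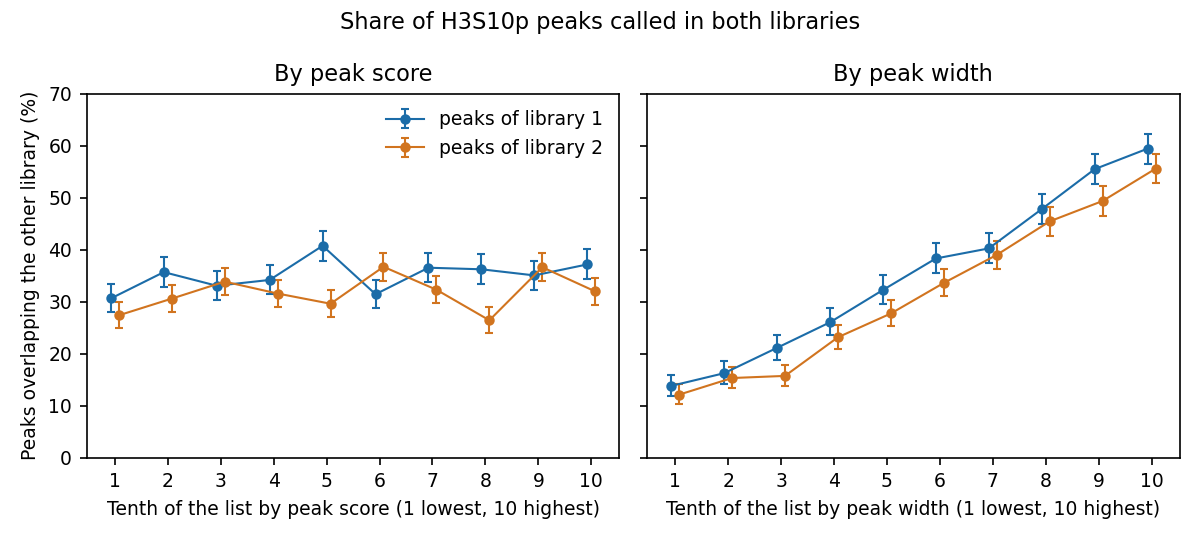
The percentage of peaks that overlap a peak of the other library (vertical axis) is plotted for 10 equal groups of each list ordered by peak score (left) or peak width in bp (right); points are the peaks of library 1 (blue) and library 2 (orange) and bars are 95% Wilson intervals. Along width the share climbs from 13.8% to 59.4% in library 1 and from 12.1% to 55.5% in library 2, while along score no group of either library lies below 26.4% or above 40.7%.

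Peaks were spread unevenly over the chromosomes, with a similar order in both libraries. Chromosome 11 was the densest, at 8.33 ± 0.54 peaks per Mb (mean ± SD, n = 2 libraries), followed by chromosomes 17 (6.42 ± 0.53) and 19 (6.30 ± 0.18). Chromosomes 14 (2.83 ± 0.39) and 3 (2.93 ± 0.21) were the sparsest autosomes. Chromosome X held 0.80 ± 0.03 peaks per Mb, from 127 peaks in library 1 and 134 in library 2, which was 0.167 times the autosomal density. Counting only peaks called in both libraries, 25 in library 1 and 26 in library 2, the ratio was 0.0957 and 0.0994. The upper 95% bound for X was 0.925 peaks per Mb in library 1 and 0.971 in library 2, below the lowest lower bound of any autosome (2.27 and 2.80). Density correlated between the libraries across the 20 chromosomes with Pearson's r = 0.99 and Spearman's rho = 0.98, each with a permutation p of 1e-05, the smallest the resamples can give. Without chromosomes X and 11, the ones farthest from the median, r was 0.98.

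**Figure D2:**
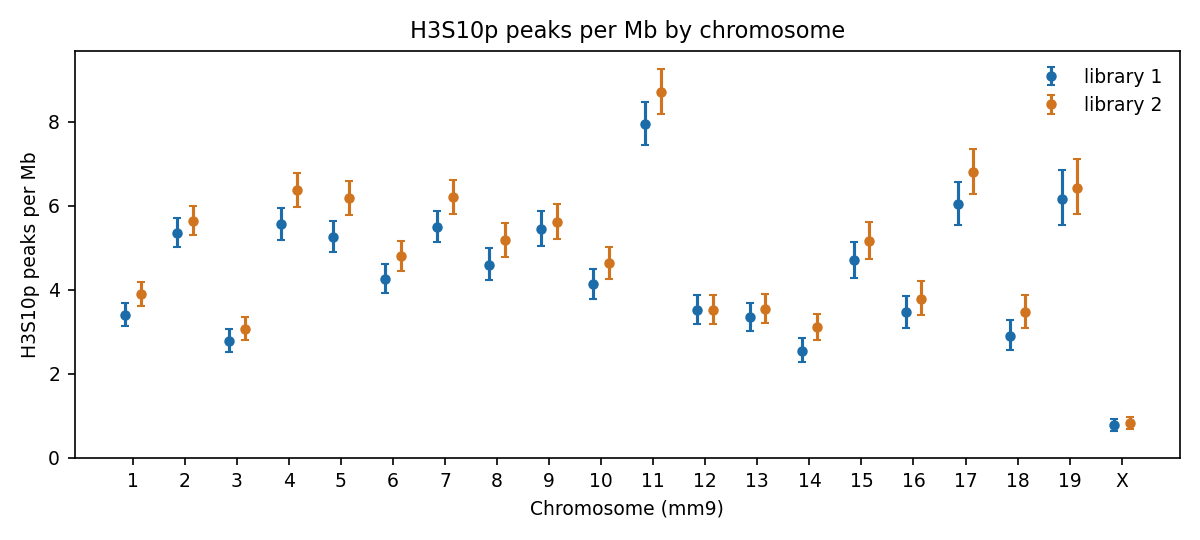
H3S10p peaks per Mb (vertical axis, from 0) are shown for each mm9 autosome and X (horizontal axis) in library 1 (blue) and library 2 (orange), with exact Poisson 95% intervals as bars. Chromosome 11 is highest in both libraries (7.95 and 8.71) and chromosome X lowest (0.777 and 0.820).

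At a finer scale, the 3 densest 1 Mb windows by the mean of the libraries were on chromosomes 10 and 7. The window from 79000001 to 80000000 on chromosome 10 held 39 and 59 peaks in the libraries, its neighbour from 80000001 to 81000000 held 47 and 45, and chromosome 7 from 52000001 to 53000000 held 44 in each. Chromosome 17 from 27000001 to 28000000 came next with 35 and 52, named after its values were seen, and in library 2 it held more peaks than the windows with 45 and 44. The median window held 2 peaks in library 1 and 3 in library 2, and 366 of 2586 windows (14.2%) held none in either. The windows were ranked alike in the libraries (Spearman's rho = 0.86 across windows). Peaks also lay close together: 21.9% of library 1 peaks and 24.5% of library 2 peaks had a neighbour within 10 kb. Random placement gave 9.57 ± 0.39% and 10.5 ± 0.38% (SD over 1000 placements), so clustering was 2.29 and 2.33 times higher, with a one-sided random-placement permutation p of 0.001 for each library, the smallest these placements can give. Random placement does not keep the regional differences in density.

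The series title names pericentric heterochromatin, so density near the centromeric end was examined. Mouse chromosomes carry the centromere at their start, and the satellite arrays themselves lie in the unassembled part, so only flanking sequence could be measured. The first 10 Mb of assembled sequence held 3.80 ± 3.22 peaks per Mb (mean ± SD over 20 chromosomes, libraries averaged) against 4.62 ± 1.70 in the rest. The difference of -0.83 ± 3.28 peaks per Mb did not pass the two-sided sign-flip permutation test (p = 0.295), although 16 of 20 chromosomes were less dense at the start. Chromosome 19 went the other way by far, with 15.8 peaks per Mb in its first 10 Mb and 4.33 in the rest. Without it, a setting added after seeing the data, the difference was -1.47 ± 1.59 peaks per Mb (permutation p = 0.00102), so this single chromosome decided the call. With the first 20 Mb in place of 10 Mb the difference passed the test too (-1.37 peaks per Mb, permutation p = 0.0201). With the first 5 Mb it was 0.28 peaks per Mb (permutation p = 0.918), although 14 chromosomes were less dense there and 6 denser.

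Directly at the assembled start, peaks gathered on chromosomes 9 and 11. The first 0.2 Mb held 8.50 peaks per Mb in library 1 (34 peaks, exact Poisson interval 5.89 to 11.9) and 8.25 in library 2 (33 peaks, 5.68 to 11.6). Of these peaks, 26 in each library were shared (76.5% and 78.8%), more than the 35.1% and 31.7% over the whole lists. Chromosome 9 carried 12 of them in library 1 and 10 in library 2, and chromosome 11 carried 13 and 12. The other chromosomes together held 9 peaks in library 1 (1.14 to 4.75 per Mb) and 11 in library 2 (3.06 per Mb, 1.53 to 5.47), and 5 of them in each library were shared (55.6%, Wilson interval 26.7 to 81.1%, and 45.5%, 21.3 to 72.0%). The high density at the start thus rests on chromosomes 9 and 11. Whether the high share of recurring peaks rests on them too cannot be told from so few peaks on the other chromosomes. Between 12 and 14 Mb from the start, density was 1.60 peaks per Mb (1.23 to 2.04) in library 1 and 1.85 (1.45 to 2.32) in library 2. Density did not simply fall with distance: it was 5.98 (5.24 to 6.78) and 6.75 (5.97 to 7.61) peaks per Mb between 28 and 30 Mb, and between 36 and 38 Mb it was 2.25 (1.81 to 2.77) in library 1, with an interval of 1.59 to 2.49 in library 2.

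**Figure D3:**
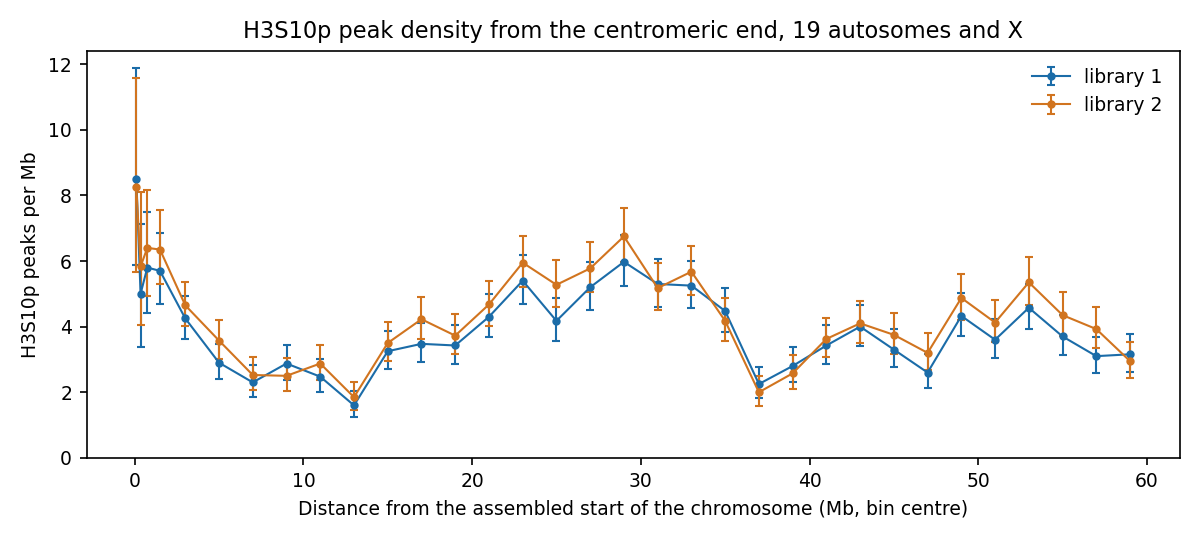
H3S10p peaks per Mb (vertical axis, from 0) are plotted against distance from the assembled start of the chromosome in Mb, pooled over 19 autosomes and X, for library 1 (blue) and library 2 (orange), with exact Poisson 95% intervals as bars. Both libraries start at 8.50 and 8.25 peaks per Mb in the first 0.2 Mb, a level set by chromosomes 9 and 11, reach 1.60 and 1.85 between 12 and 14 Mb, rise to 5.98 and 6.75 between 28 and 30 Mb and drop again between 36 and 38 Mb (2.25 in library 1).

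The RNA comparison asked which genes changed when Aurora kinases were inhibited for 48 hours. All 10 genes in the authors' deposited table were higher after ZM-447439, by at least 2-fold in their listed mean log2 fold change, and none was lower. Pla2g4f (gene 271844), a cytosolic phospholipase A2, has a log2 fold change of 3.65 in the authors' deposited table (NE 0.0104 treated against 0.00083 untreated, p = 0.00379). That value rests on 1 of its 2 transcripts. Its untreated NE is the lowest of the 10 genes, so the fold change is taken against a very small signal. Ddah1 (gene 69219), an enzyme that breaks down asymmetric dimethylarginine, had the smallest p in the authors' deposited table, at 2.75e-08, with a log2 fold change of 1.86 over 5 of its 10 transcripts.

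A further 7 genes of the authors' deposited table rose between 2-fold and 3-fold. On the log2 scale, the authors' deposited table gives 1.57 for Cd109, a surface antigen that binds TGF-beta, and 1.32 for Ano3, of the anoctamin membrane protein family. Scn3b, a sodium channel beta subunit, stands at 1.305 over 4 of its 8 transcripts and the T cell co-stimulatory ligand Cd80 at 1.30 in the authors' deposited table. Plekhg1 stands at 1.06 in the authors' deposited table, beside the tyrosine phosphatase Ptpn14 at 1.05 and the secreted protease inhibitor Serpine2 at 1.01. In each of the 10 genes, the means in the authors' deposited table lay farther apart than the sum of their listed SDs. The SDs in the authors' deposited table have 3 decimals, so that of Plekhg1 in untreated cells and both of Pla2g4f read 0.000, which leaves their spread unknown below that rounding.

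None of the 10 genes belonged to the 10 lists fixed beforehand. These covered satellites and repeats, pluripotency factors, germ layer and trophoblast genes, p53 targets, the chromosomal passenger complex with the Aurora kinases, mitotic genes, heterochromatin factors, genes of the 2-cell-like state, replication-dependent histones, and fibroblast or feeder markers. The authors listed 1 row per gene, matched here by symbol, so satellites and repeats could hardly have appeared. With only 10 genes listed, few members of any list would be met by chance. Their absence is therefore no evidence that these groups did not respond. Every p in the authors' deposited table was at most 0.00946 and the log2 fold changes listed for changed transcripts were at least 1.002, so the table held only genes past such limits and says nothing about the size of change of genes outside it or of the other transcripts of these genes. For 6 of the 10 genes, the authors' deposited table rests on a single changed transcript, and over all genes 22 of 81 annotated transcripts were counted as changed.

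**Figure D4:**
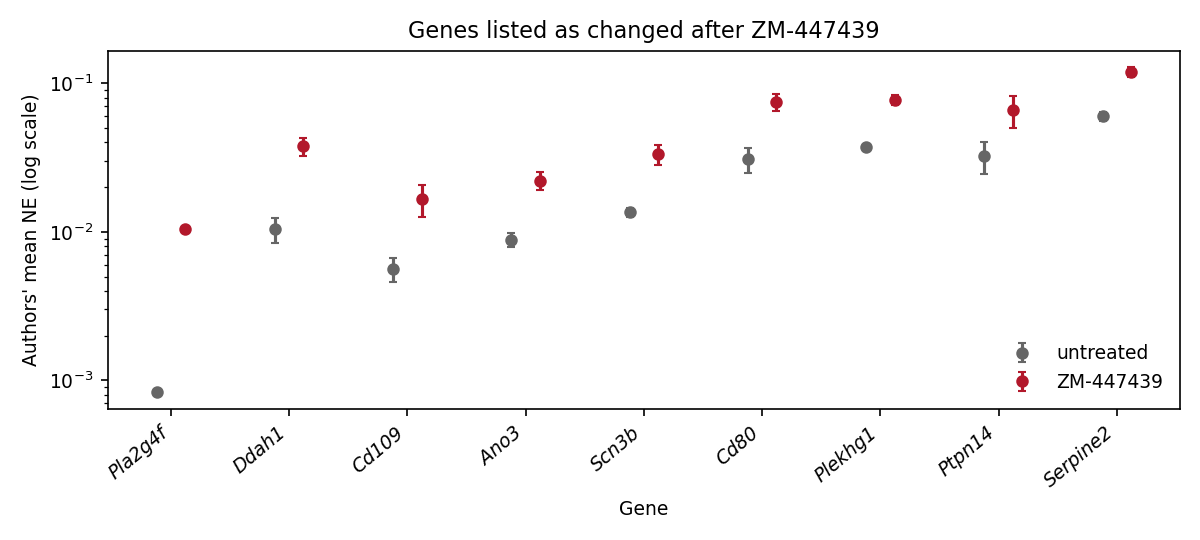
The authors' mean NE (vertical axis, log scale) is shown for 9 of the 10 genes of the authors' deposited table in untreated cells (grey) and after ZM-447439 (red), with the authors' SD as bars. The treated mean lies above the untreated mean for all 9 genes drawn, with the widest gap for Pla2g4f (0.0104 against 0.00083).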

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

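Of the tests in this part, the one on peak-poor autosomal regions was written before its result was seen, and the remaining tests were chosen after the chromosome counts were known. Chromosome Y, which no comparison of chromosomes used, carried 4 peaks in each library. That is above the limit of 3 set for flagging, which is not a test. A single pair of them overlapped, at 2860259 to 2860583 in library 1 and 2860179 to 2860633 in library 2. Library 1 also had 1 peak on the mitochondrial sequence, from 2267 to 3609, and library 2 had 0.

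Peaks were scarce on chromosome X. Spread between chromosomes of equal copy number is argued against, since X lay 5.58 SD (library 1) and 5.93 SD (library 2) below the autosomal mean, on the log2 scale of peaks per Mb with the SD over 19 autosomes, while the farthest autosome, chromosome 11, lay 2.24 and 2.28 SD from the mean of the other autosomes. Regions as poor in peaks as X were rare on autosomes: only 5 of 232 autosomal 10 Mb windows (2.16%) had as few peaks as the median X window. That window held 7 peaks against an autosomal median of 33. The windows were not matched for any property of their sequence, so this count cannot tell whether the makeup of X accounts for the scarcity. A single copy of X in these cells, whose sex the labels do not give, stays open as a hypothesis. The 4 peaks called on chromosome Y in each library bear on the sex of the cells. Whether they reflect a Y chromosome was not tested. X stood at 16.7% of the autosomal density. With only peaks called in both libraries counted, on X and on autosomes, the ratio was 0.0957 and 0.0994. How many peaks would be lost with fewer copies cannot be computed while the scale of the scores is not named. Base composition and mappability of X were not tested, and no biological explanation was tested, since the design names no second ChIP group.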

How the results depend on the processing

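The settings on peak width, random shifts, scores over 150, X among shared peaks and single chromosomes were added after seeing the data. Of the results recomputed under alternatives, the excess of shared peaks over random placement, the rank order of chromosomes between libraries, and clustering at 5 and 50 kb kept their direction and side of the threshold. The share of library 1 peaks found in library 2 ranged from 19.5% (upper 50% of each list by score) to 39.6% (wider 50%). With those settings the number of shared peaks was 1077 and 2192 instead of 3881, from lists limited to 5533 and 6130 peaks. In the upper 50% by score the density of X was 0.125 times that of autosomes (0.167 with all peaks, 0.0975 with peaks called in both libraries) and the median width 255 bp (308 bp); the cause was not tested. The difference in density at the centromeric end was 0.28 peaks per Mb in the first 5 Mb, the opposite sign to -0.83 in the first 10 Mb, and -1.37 in the first 20 Mb, where it passed the test; the cause was not tested. In the first 5 Mb, 14 chromosomes were still less dense than in the rest and 6 were denser. Without chromosome 19 the difference in the first 10 Mb was -1.47 and passed, and leaving out each of the other 19 chromosomes gave -0.98 to -0.66 (permutation p from 0.225 to 0.455). Leaving out either ChIP library gave -0.91 and -0.74 there. The stricter p and fold limits on the RNA table could not change its count of 10 genes, since all of them lie past both by the listed values. By the ratio of its NE means, Serpine2 stood at a log2 value of 0.997, just under the fold limit. No paired analysis was possible because the RNA table gives group means and not values per library. For the same reason, the alternatives for counts and normalized values per library were not run, nor was that on promoters, which needs an mm9 annotation. Read depth is unknown, so peaks called in a single library cannot be separated into absent and undetected ones.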

Other observations

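The tests in this part were chosen after the data had been seen. Those on peak width were written for a pattern already seen, but before their own results were. Peaks called in a single library were distributed alike over the genome. Over 1 Mb windows, the numbers of library 1-only and library 2-only peaks had a Spearman correlation of 0.71 across windows. Of the library 1-only peaks, 366 (5.09%) had the centre of a library 2 peak within 1000 bp, against a mean of 180 after random shifts of up to 500 kb, and of the library 2-only peaks 371 (4.43%) against 188 (one-sided random-shift permutation p = 0.005 for each, the smallest that 200 shifts can give). Within 5000 bp the counts were 1175 against 830 for library 1 and 1238 against 885 for library 2. Shifts of this size do not keep clustering at shorter distances, so the excess cannot be told apart from it. The share of peaks found in both libraries was 31.1% (29.3 to 32.9%) for clustered peaks against 36.2% (35.2 to 37.2%) for peaks standing alone in library 1, and 27.6% (26.0 to 29.2%) against 33.0% (32.1 to 34.0%) in library 2, with Wilson intervals and no test of the difference. Median widths were 286 and 259 bp for clustered peaks against 329 and 309 bp.

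The far ends of the chromosomes were denser than the remainder in the mean. The last 10 Mb held 6.69 ± 4.71 peaks per Mb (mean ± SD over 20 chromosomes) against 4.46 ± 1.61 in the rest, a difference of 2.23 with a sign-flip permutation p of 0.0252, higher on 14 of 20 chromosomes. Leaving out chromosome 4, 8, 11 or 15 in turn gave differences of 1.83, 1.90, 1.80 and 1.94 peaks per Mb, with p values of 0.0526, 0.053, 0.0528 and 0.052 in the same permutation test, just above the threshold of 0.05.

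The widest peak of each list lay at one place on chromosome 17, from 39979901 to 39985869 (5969 bp) in library 1 and from 39979916 to 39983743 (3828 bp) in library 2. Library 2 had a further peak there, from 39984739 to 39985867 (1129 bp), so its calls together spanned nearly the same region as the single call of library 1. From general knowledge, not from an annotation used here, mm9 holds at this place an assembled copy of the 45S ribosomal RNA precursor, a gene present in many copies in the cell.

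A pair of patterns within the report's peaks were weighed. The strongest peaks recurred with borders a median of 4 bp apart among the top 20 and 89 bp among the other shared pairs. Reads from many repeat copies placed on the few copies in the assembly are a candidate explanation that stays open: 40% of the top 20 (8 peaks at 4 of the 15 loci) lay within 0.2 Mb of an assembled chromosome start, against 0.464% of the other 3877 pairs (18 pairs). No p is given, since this share prompted the comparison, neighbouring peaks are not independent and no repeat annotation was used here. Real enrichment of H3S10p at such repeats would give the same picture, and was not tested, since no input library was analysed here. The 5 shared peaks with the highest mean score lay outside these chromosome starts, so the comparison does not bear on them.

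The other pattern was that wide peaks recurred more often than narrow ones. Chance overlap of wider intervals is argued against as the sole explanation: the widest 25% were shared 101 and 106 times more often than under random placement. With centres required to lie within 100 bp they were still shared 2.42 and 2.84 times as often as the narrowest 25%. By the 1 bp overlap rule these ratios were 3.45 and 3.74, so part of the difference went with that rule. Location in peak-poor regions is argued against too, since the ratio of widest to narrowest was 3.28 or more in each tertile of local peak density in both libraries. A hypothesis that stays open, among others not examined, is that many narrow peaks may be built from few reads over one background level. That would give them a few fixed scores. No biological explanation was tested. Scores held by 10 or more peaks made up 94.0% of the narrowest 25% in library 1 and 94.5% in library 2, against 2.02% and 2.28% of the widest 25%, at least 41.4 times as frequent, and 399 peaks of library 2 shared the score 80.74. Such scores were held by 28.3% of shared peaks in library 1 and 31.5% in library 2. Among peaks called in a single library they were held by 54.8% and 60.0%. Since these scores go with width, their frequency does not test whether few reads keep narrow peaks from recurring.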
